A study of Mus musculus with 9 samples.

How the data were processed

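Polysome-bound mRNA of mouse oocytes was measured on 9 Affymetrix mouse whole-genome arrays, 3 each at the GV, MI and MII stage. Per the labels' protocols, mice received hCG for 0, 4 or 14 h, 48 h after PMSG, polysome-bound mRNA was purified with a column kit, reverse-transcribed and linearly amplified with a whole-transcriptome system made for degraded RNA, and the cDNA was fragmented and labelled with biotin. Values were used as the authors deposited them: 1 table with an intensity on a linear scale for each probe set and array. The method that summarised probes into probe sets, any background correction and any scaling between arrays are not given in the sources used here. The table holds no detection calls and 0 other columns of per-sample values. From the values, array medians lay between 12.39 and 13.22 and maxima between 18392 and 21038. Array medians lie at background, and the 95th percentiles differed more, from 1126 (MII 3) to 1458 (MI 1). The array files name no genome build, so no coordinates are given.

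Of 45101 probe sets in the table, 64 controls were left out. In the platform annotation, 34945 of the others had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were tested as genes. Gene identifiers were looked up in a RefSeq table of assembly GRCm38.p6, which held 18032 of the 18193 genes and changed 0 symbols. For the 9010 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays stood for the gene, and for genes that passed, other probe sets at or above the median signal of all genes are given where their sign differs in that comparison. Cyclin B1 was in the fixed panel but had no probe set with a single symbol.

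Values were transformed to log2(intensity + 16) without a filter on low signal. One linear model with the 3 stage means was fitted over all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that every contrast shared one estimate of the spread. The contrasts were MI minus GV, MII minus MI, MII minus GV and the difference between the 2 steps, with an F test over the stages. All tests of contrasts were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 18193 genes. Fold changes are on the log2(intensity + 16) scale, which understates the change of genes with low signal. Standard errors are those of the fit, and values with ± are the mean and SD of 3 arrays on the intensity scale.

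Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data and with fry, with Benjamini-Hochberg adjustment over 84 tests (28 lists in 3 contrasts). Of the 84 tests, 30 passed with the preset correlation, 0 with an estimated one and 28 with the directional test of fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes; 23 passed both camera and fry. The lists of the cell cycle were M-phase and spindle checkpoint regulators, the anaphase-promoting complex and its E2 enzymes, spindle and kinetochore, and meiotic arrest and cAMP-MAPK signalling. Those of oocyte function were regulators of translation and mRNA stability, mRNAs polyadenylated at maturation in textbook accounts, zona pellucida and oocyte growth factors, maternal-effect and subcortical complex, oocyte transcription factors, meiotic chromosome axis and recombination, and fertilisation and egg activation. Those of metabolism and protein synthesis were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, translation initiation and elongation factors, and proteasome subunits. Further lists were the PI3K-mTOR pathway, DNA replication, DNA damage and repair, histone genes, variants and chaperones, chromatin modifiers, and nuclear pore and lamina. The last were granulosa, cumulus and theca cell markers, blood, immune and endothelial markers, stress and heat-shock genes, and the endoplasmic reticulum and secretory pathway. The count of members that passed is given over all genes and adjusted over the list alone.

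Genes were named by a rule. Per contrast, it took the 10 genes with the largest rise and the 10 with the largest fall among those that passed. Their 3 arrays of one stage all had to lie beyond the 3 of the other, and their mean in the higher stage had to be at or above the median of all genes' means (an intensity of 37.5). Predicted and unnamed genes were skipped. It added a panel of 15 genes in every contrast, of which 14 were measured. Per list, it added up to 4 members with the largest change among those that passed, or the 1 with the smallest p where none did. Genes outside this rule are said to be so. The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined.

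The tests were tested on simulated data with the spread of these arrays, in 10 simulations of MI against GV over 18193 genes with 100 genes changed at each fold: 0.4% of genes changed 2-fold and 12% of those changed 4-fold were recovered, with a mean of 0.9 false calls. The changed genes were drawn only from those above the median signal. A shifted list had a camera adjusted p of 5.08e-16 and 0 of 20 unshifted lists passed. The simulated noise was independent between genes. This therefore does not show how camera with the preset correlation behaves on lists whose genes move together. One such list was oxidative phosphorylation, with an estimated correlation of 0.19. For comparisons that share arrays, unchanged stages were simulated 20 times. For the share of change present at MI, 20 simulations gave GV and MI their joint mean. Noise was independent between genes in these as well.

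The alternatives for the fit were the replicate number as a block, fits of only the 2 stages compared, and eBayes with a trend and robust settings. Arrays were also quantile normalized, centred on their median or centred on ribosomal protein genes. Genes were also summarised by the mean of their probe sets. Further alternatives were leaving out probe sets whose suffix marks them as shared between transcripts (_x_at and _s_at), testing every probe set, leaving out the lowest 40% of genes, a minimum of 2-fold, an adjusted p under 0.01, pseudocounts of 1 and 64, and leaving out each array in turn. Leaving out GV 3 and MI 3 together and scaling all arrays to the same 95th percentile were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Motifs and lengths of untranslated regions were not analysed here, since no genome or transcript sequence was used.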

Results

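Messenger RNA bound to polysomes, the ribosome-laden mRNAs that are being translated, was measured in mouse oocytes at 3 stages of meiotic maturation with Affymetrix mouse whole-genome arrays. The stages were the germinal vesicle (GV) stage, in which oocytes rest in prophase arrest, metaphase I (MI) and metaphase II (MII), at which the ovulated egg arrests. Titles, sources and stage fields of the labels name these stages, while the description of the MI samples reads pGVB, which is not explained. Oocytes were collected 0, 4 and 14 h after human chorionic gonadotropin (hCG), given 48 h after PMSG, a gonadotropin that stimulates follicle growth. Each stage had 3 arrays, 9 in all, and the median intensity of an array lay between 12.39 (GV 1) and 13.22 (MII 3). Between 53.1% and 54.8% of the probe sets of an array lay below an intensity of 16, so most probe sets gave signal near background. The number of arrays limits the precision of every value. The labels call the samples biological replicates and speak of 3 independent sample sets, but nothing says whether they came from separate animals, so the p-values measure only the spread between these samples, which may be technical. A signal on polysomes depends on how much of an mRNA a cell holds and on how much of it is loaded with ribosomes, and arrays of total RNA were not analysed here.

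Arrays of GV and MI oocytes resembled each other about as much as arrays of one stage, and the MII arrays stood apart. Over all probe sets except controls, the mean Pearson correlation between a GV and an MI array was 0.901, against 0.909 between GV arrays, 0.901 between MI arrays and 0.906 between MII arrays. It was 0.833 between MI and MII arrays and 0.805 between GV and MII arrays. These correlations run across probe sets, which are not independent replicates. The moderated F test of limma called 2108 of 18193 genes as different among the 3 stages, with 4313 at an unadjusted p under 0.05. That count was 1373 without MII 1, 1373 without MII 2 and 1140 without MII 3.

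The comparison of MI with GV asks which polysome-bound mRNAs change in the first 4 h after hCG, as the nuclear envelope breaks down and the first spindle forms. No single gene passed the test at this step, and the values of the fixed panel are given first. Mos, the kinase that activates the MAPK pathway in oocytes, had a mean intensity of 929 ± 329 in GV and 1499 ± 471 in MI (SD, n = 3 each; log2 change 0.70, SE 0.36, adjusted p = 0.783). Tex19.1, a germ cell gene, went from 1695 ± 769 to 3542 ± 506 (log2 change 1.14, SE 0.31, adjusted p = 0.484). Tpx2, a spindle assembly factor, went from 1163 ± 171 to 1970 ± 175 (log2 change 0.76, SE 0.21, adjusted p = 0.51). Dazl, an RNA-binding protein of germ cells that promotes translation, went from 857 ± 45.1 to 1113 ± 280 (log2 change 0.35, adjusted p = 0.864). Dazl, Tpx2 and Tex19.1 are genes this study is known for, so their direction is not independent evidence in any of the comparisons. Among the other panel genes, the log2 change was 0.15 for Plat (tissue plasminogen activator), 0.46 for Bub1b (a spindle checkpoint kinase), 0.41 for Btg4 (an adaptor of mRNA deadenylation) and 0.39 for Cpeb1 (the cytoplasmic polyadenylation element binding protein). It was -0.36 for Zp1, -0.36 for Zp2, -0.15 for Zp3, -0.18 for Gdf9, -0.01 for Bmp15 and -0.51 for Nlrp5, and none of these 14 genes passed the test.

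By list, the M-phase and spindle checkpoint regulators rose as a group from GV to MI, with 24 of 34 measured members above 0 and a median log2 change of 0.27 (camera adjusted p = 0.00144; adjusted p = 0.209 with an estimated correlation; adjusted p = 0.0576 by fry). Mastl, the kinase that restrains the phosphatase PP2A in M phase, had the smallest p of the list and a log2 change of 0.87 (390 ± 91.2 in GV, 716 ± 104 in MI, n = 3 each; adjusted p = 0.467; other probe sets 0.43 and -0.08). The list of mRNAs polyadenylated at maturation in textbook accounts also rose as a group, with all 6 measured members above 0, a median of 0.49 and Slbp, the histone mRNA stem-loop binding protein, at 0.57 (camera adjusted p = 0.00103; adjusted p = 0.209 with an estimated correlation; adjusted p = 0.00752 by fry). Of the 5 lists that passed camera at this step, it alone passed fry. Its median was 0.32 without GV 3 and 0.31 with the mean of all probe sets, and it passed camera in both. Adjusted over the list alone, 2 of these 6 genes passed. The mitochondrial ribosomal proteins had a median of -0.16 (camera adjusted p = 0.0153; adjusted p = 0.431 with an estimated correlation) and the oxidative phosphorylation list one of -0.18 (camera adjusted p = 0.0153; adjusted p = 0.574 with an estimated correlation). The translation initiation and elongation factors had a median of -0.07 (camera adjusted p = 0.035; adjusted p = 0.391 with an estimated correlation). The adjusted p by fry was 0.38, 0.592 and 0.302 for these 3 lists. Their camera calls held on arrays centred on their median or scaled to the same 95th percentile (the latter chosen after seeing the data), and 2 of them, for oxidative phosphorylation and for initiation and elongation, were lost after quantile normalization and with pseudocount 1. With the mean of all probe sets the mitochondrial ribosomal and the initiation and elongation lists lost theirs (adjusted p = 0.0532 and 0.121). On arrays centred on ribosomal protein genes their medians were 0.14, 0.15 and 0.21, beside a shift of 0.13 in the median of all genes, and none passed. Bright genes moved by more than that shift, so this does not compare the lists with genes of like signal. Leaving out 1 array also cost these lists their calls. The mitochondrial ribosomal list was lost without GV 1 (camera adjusted p = 0.0628), GV 3 (0.0854) or MI 3 (0.121), while its median was -0.29 without GV 2, -0.34 without MI 1 and -0.30 without MI 2. The oxidative phosphorylation list was lost without GV 1 (0.145), GV 3 (0.0718) or MI 3 (0.214), its median being -0.0091 without MI 3. MI 3 stood apart from the other 8 arrays in the median of the granulosa, cumulus and theca markers (5.72 on the log2 scale, against 4.77 to 4.97) and in control signal (geometric mean 5143, against 2000.53 to 3588.65). The initiation and elongation list was lost without GV 2 (0.294), GV 3 (0.0525), MI 1 (0.0565) or MI 2 (0.102). Its medians in these runs were -0.09, -0.11, -0.12 and -0.13, and it was -0.14 without GV 1, where the list passed. The call was also lost without the lowest 40% of genes (camera adjusted p = 0.0724).

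Single members with the largest separation at this step, 1 per list, also stayed short of the threshold. Ndc80, a kinetochore protein that holds microtubules, had 221 ± 48.6 in GV and 920 ± 127 in MI (log2 change 2.00, adjusted p = 0.194, n = 3 each). Anapc10, a subunit of the anaphase-promoting complex, had 97.4 ± 60.3 and 712 ± 246 (log2 change 2.79, adjusted p = 0.208). Atp5o, an ATP synthase subunit, had 2535 ± 278 and 956 ± 122 (log2 change -1.39, adjusted p = 0.194). Izumo1r, the egg receptor for sperm Izumo1, had a log2 change of -1.30 (adjusted p = 0.292), and Ybx2, a germ cell mRNA-packaging protein, one of -1.42 (adjusted p = 0.353). No gene of 18193 passed limma's test from GV to MI in either direction, while 1308 had an unadjusted p under 0.05 where chance gives 910, and the smallest adjusted p was 0.177. In simulated data with the spread of these arrays and 100 genes above the median signal changed at each fold, this comparison recovered 0.4% of genes changed 2-fold and 12% of genes changed 4-fold. Changes of that size in so few genes were thus mostly not detectable here. The share recovered depends on how many genes change, and other numbers were not simulated.

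**Figure D1:**
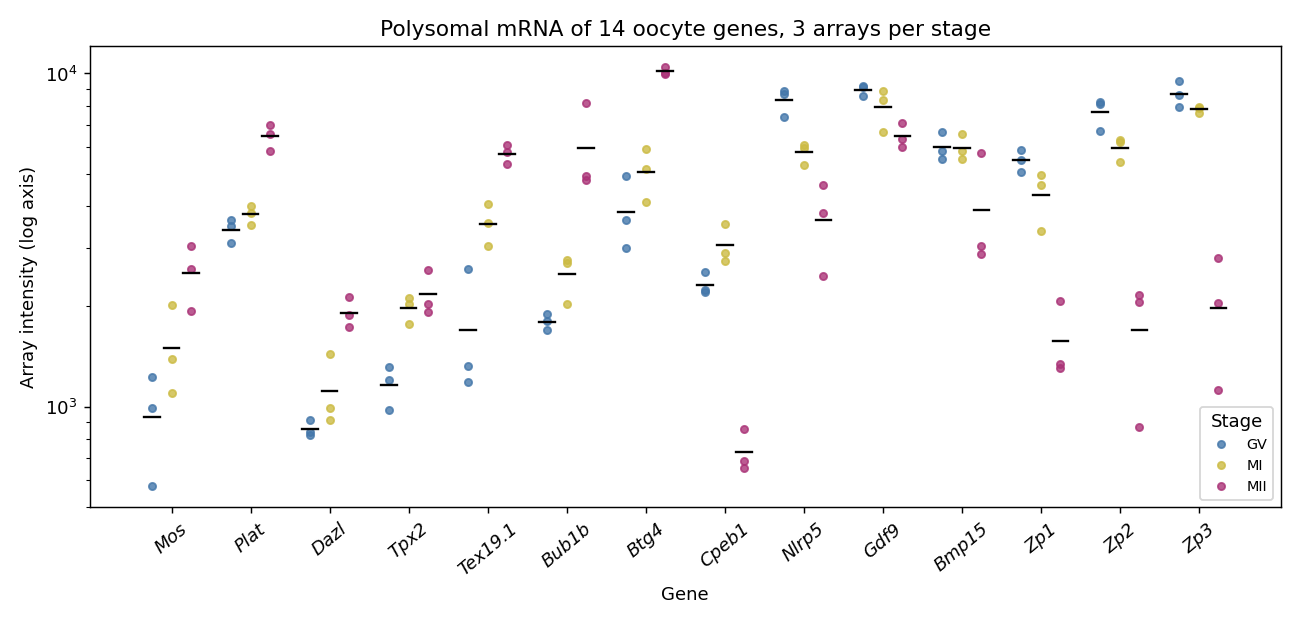
Array intensity (log axis) of the 14 measured panel genes, with 1 point per array (3 each at GV, MI and MII) and a black bar at the mean of each stage. Bub1b, Btg4 and Plat sat highest in MII, and Cpeb1 and the zona pellucida genes lowest in MII; on arrays centred on ribosomal protein genes all genes shift upward, and the log2 changes of Cpeb1, Zp1, Zp2 and Zp3 from MI to MII become 1.23, 1.82, 1.36 and 1.21, below the shift of 2.12 in the median of all genes.

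The comparison of MII with MI asks which polysome-bound mRNAs change between 4 and 14 h after hCG, as oocytes complete the first division and arrest again. Most of what moved here fell: mRNAs of ribosomal proteins, of the mitochondrial respiratory chain, of the proteasome and of several cell cycle regulators were lower on MII arrays, while a smaller set rose. Cdk1, the kinase that drives entry into M phase, fell from 4722 ± 2299 in MI to 76.9 ± 44.3 in MII (SD, n = 3 each; log2 change -5.67, SE 0.56, adjusted p = 0.00174). Cpeb1 fell from 3051 ± 420 to 732 ± 109 (log2 change -2.04, SE 0.20, adjusted p = 0.00182), and its log2 change was 1.23 on arrays centred on ribosomal protein genes, where the sign turns but the value lies below the shift of 2.12 in the median of all genes. Bub1b rose from 2493 ± 404 to 5967 ± 1906 (log2 change 1.22, SE 0.26, adjusted p = 0.0257) and its other 2 probe sets moved by 0.98 and 1.60. Bub1b lost its call without MI 1 (adjusted p = 0.0611), MI 2 (adjusted p = 0.0888) or MII 3 (adjusted p = 0.0597).

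In all, 462 genes rose and 1233 fell from MI to MII by limma's test, of which 437 and 1219 changed at least 2-fold, and each of these had its 3 arrays of one stage beyond the 3 of the other. Chance gives this for 10% of genes, but genes that passed a test on the same arrays were bound to exceed that share. The genes that rose made up 27.3% of those called, against 42.2% after quantile normalization, 41.3% with arrays scaled to the same 95th percentile (chosen after seeing the data) and 99.5% on arrays centred on ribosomal protein genes. That last scaling moved the median of all genes by 2.12 from MI to MII and by 2.23 from GV to MII on the log2 scale, so signs turn there by construction. Bright genes moved by more than the median gene, as Gdf9 from -0.28 to 3.01, so a value above those shifts does not place a bright gene or list above others of like signal. The count of genes that rose was 828 after quantile normalization, 781 with the same 95th percentile, 707 over every probe set and 183 with pseudocount 1. It was 300 without MI 1, 206 without MI 2, 304 without MI 3, 235 without MII 1, 260 without MII 2 and 187 without MII 3. The count of genes that fell was 725 without MI 1, 640 without MI 2 and 744 without MII 3. Genes that rose started lower than genes that fell, with a median MI intensity of 231.8 against 988.7 and 148 of 462 against 32 of 1233 below 100, though above the median of all genes' means, 37.5. The same MI arrays enter the calls, and a gene near background has little room to fall, so this order was partly fixed in advance. Since fold changes were taken on log2(intensity + 16), they understate the change of genes near background.

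Among the genes with the largest rises from MI to MII, Poglut2, an endoplasmic reticulum glucosyltransferase, went from 42.4 ± 22.4 to 2140 ± 1622 (log2 change 5.03, SE 0.52, adjusted p = 0.00202, n = 3 each). Efcab7, which anchors a signalling complex at the base of cilia, rose from 36.1 ± 43.2 to 750 ± 98.6 (log2 change 4.18, adjusted p = 0.00748), and Osbpl1a, a lipid-binding protein of endosomes, from 34.8 ± 18.3 to 548 ± 175 (log2 change 3.49). Pdlim5, a cytoskeletal adaptor, rose by 3.76 on the log2 scale. Mtbp, a protein of replication origin firing, rose by 4.22 (adjusted p = 0.0191), a call lost without MI 2, MI 3, MII 1 or MII 3 (adjusted p from 0.0526 to 0.0689). Fbxo15, an F-box protein of early embryos, rose by 3.64 (adjusted p = 0.0222), a call lost without the same 4 arrays (adjusted p from 0.0613 to 0.0765). Rps6ka5, a chromatin kinase, rose by 3.49, a call lost without MI 2 (adjusted p = 0.0503) or MII 3 (adjusted p = 0.057). Prkci, an atypical protein kinase C of cell polarity, rose by 3.77, but passed in only 1 of the 9 fits that left out 1 array, the one without MI 1 (adjusted p from 0.0521 to 0.149 in the others).

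Among the largest falls, Ndufb7, a subunit of respiratory complex I, went from 2187 ± 426 in MI to 36.5 ± 7.88 in MII (log2 change -5.38, SE 0.22, adjusted p = 0.000145, n = 3 each), and its other probe set fell by 3.05. Spc24, a partner of Ndc80 at the kinetochore, fell from 3167 ± 690 to 84.3 ± 116 (log2 change -5.62). Mrps28, a mitochondrial ribosomal protein, fell from 1708 ± 853 to 27.8 ± 37.4 (log2 change -5.52), and Commd9, a protein of endosomal sorting, from 1401 ± 94.7 to 24.4 ± 28.6 (log2 change -5.35; other probe sets -4.20 and -2.49). Snapc5, a subunit of the small nuclear RNA activating complex, fell by 5.39 on the log2 scale, a call lost without MI 2 (adjusted p = 0.0515). For 4 of the 10 genes with the largest falls another probe set lay above 0. Tsc22d4 had -5.91 at its brightest probe set and 0.89 at the other, and Tox2 had -5.69 and 0.63. Pum3 had -5.69 against 0.59 and -0.60, and Fuca1 had -5.43 against -0.87, -1.19 and 0.51. Without MI 2 the calls of Pum3 (adjusted p = 0.0513) and Fuca1 (adjusted p = 0.0503) were lost, and that of Pum3 also without MII 3 (adjusted p = 0.0506). Over all called genes, 292 of 320 other probe sets at or above the median signal had the sign of the rise and 638 of 759 that of the fall. No such share was taken for genes not called, and the mean signal that picked these probe sets includes the MII arrays.

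Ribosomal protein mRNAs fell together from MI to MII: 38 of the 50 measured cytosolic ribosomal protein genes fell, none rose and 12 did not pass (43 fell adjusted over the list alone). The list median fell by 3.00 on the log2 scale, or 8.01-fold (camera adjusted p = 5.1e-29; adjusted p = 0.115 with an estimated correlation). Rpl38 fell from 6497 ± 1137 to 303 ± 186 (log2 change -4.58, SE 0.51), Rpl27a from 2793 ± 759 to 125 ± 102 (log2 change -4.52; other, dimmer probe set 0.45) and Rpl10a from 3843 ± 379 to 187 ± 99.1 (log2 change -4.35), with n = 3 each. The list median of each MII array, at most 8.55 on the log2 scale, lay below that of every GV and MI array, at least 11.33. Of the 82 oxidative phosphorylation genes, 59 fell, none rose and 23 did not pass (69 fell and 1 rose adjusted over the list alone). Their median was -3.06 (camera adjusted p = 6.68e-31; adjusted p = 0.115 with an estimated correlation). Ndufb5 of complex I fell from 2795 ± 1164 to 85.4 ± 22.1 (log2 change -4.71) and Uqcr10 of complex III from 2523 ± 1788 to 79.6 ± 69.8 (log2 change -4.73). Of the 76 mitochondrial ribosomal protein genes, 26 fell, 1 rose and 49 did not pass (43 fell and 1 rose adjusted over the list alone). Their median was -1.64 (camera adjusted p = 1.33e-14; adjusted p = 0.115 with an estimated correlation). Mrps18c fell from 1033 ± 140 to 40.3 ± 21.6 (log2 change -4.28). The member that rose was Mrpl3, chosen after its values were seen, from 374 ± 53.8 to 1856 ± 78.2 (log2 change 2.27). On arrays centred on ribosomal protein genes the medians of these 3 lists were 0.0021, 0.04 and 1.41, above 0 but below the shift of 2.12, and all 3 still passed as lower than other genes.

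**Figure D2:**
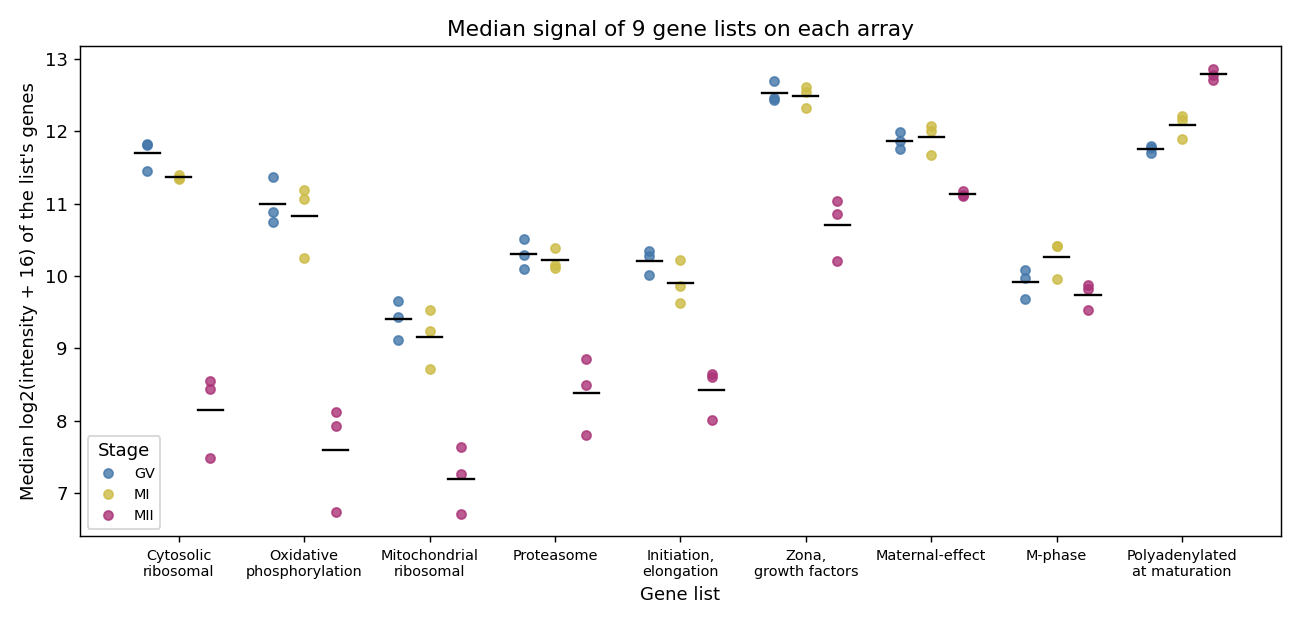
Median log2(intensity + 16) over the genes of 9 fixed lists, with 1 point per array (3 each at GV, MI and MII) and a black bar at the mean of the 3 points. The 3 MII arrays lie below every GV and MI array for the first 7 lists, as between 7.48 and 8.55 for cytosolic ribosomal proteins, and above them for the mRNAs polyadenylated at maturation; centring on ribosomal protein genes moves all genes upward, by construction, and the zona and maternal-effect lists from MI to MII to medians of 2.49 and 2.74.

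Other lists of the translation and protein turnover machinery fell less from MI to MII. Of 58 initiation and elongation factors, 16 fell, none rose and 42 did not pass (27 fell and 5 rose adjusted over the list alone). Their median was -0.84 (camera adjusted p = 4.57e-05; adjusted p = 0.209 with an estimated correlation). Eif3k fell from 3142 ± 400 to 199 ± 102 (log2 change -3.98, n = 3 each), Eif3m changed by -3.95 and Eif1b fell from 4818 ± 264 to 384 ± 72.1 (log2 change -3.61). Of 39 proteasome subunits, 16 fell, none rose and 23 did not pass (19 fell adjusted over the list alone). Their median was -1.27 (camera adjusted p = 1.39e-09; adjusted p = 0.136 with an estimated correlation). Psmb4 fell from 2596 ± 190 to 240 ± 143 (log2 change -3.57) and Psmb5 from 607 ± 378 to 22.4 ± 25.7 (log2 change -4.07). Of 22 genes of the tricarboxylic acid cycle, 6 fell, none rose and 16 did not pass (9 fell and 1 rose adjusted over the list alone). Their median was -0.81 (camera adjusted p = 0.0037; adjusted p = 0.22 with an estimated correlation). Mdh2, mitochondrial malate dehydrogenase, fell from 2124 ± 208 to 190 ± 121 (log2 change -3.62). These 3 calls were lost on arrays centred on ribosomal protein genes, where the medians were 2.11, 1.37 and 2.42 beside the shift of 2.12. That scaling lifts bright genes by more than the median gene. The loss therefore does not tell how these lists moved against genes of like signal. With the mean of all probe sets the initiation and elongation median was -0.48 and the tricarboxylic acid median -0.44, and the latter list did not pass without the lowest 40% of genes (adjusted p = 0.0553).

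Cell cycle genes moved both ways from MI to MII. Of 34 M-phase and spindle checkpoint regulators, 2 rose, 6 fell and 26 did not pass (6 rose and 10 fell adjusted over the list alone), and the list as a whole did not pass (median -0.04, mean -0.53, camera adjusted p = 0.469). Beside Cdk1, Ensa, the small PP2A inhibitor switched on by Mastl, fell from 650 ± 112 to 8.11 ± 2.68 (log2 change -4.78, adjusted p = 0.00026, n = 3 each), its relative Arpp19 fell by 2.48 (other probe sets -1.40 and 1.71), and Cdc25b, the phosphatase that activates Cdk1, fell from 1742 ± 18.8 to 75.4 ± 48.2 (log2 change -4.42). The members that rose were Bub1b and Mastl, the latter chosen after its values were seen, from 716 ± 104 to 1861 ± 30.0 (log2 change 1.37, adjusted p = 0.0105; other probe sets -0.47 and 0.31). Of 18 genes of the anaphase-promoting complex and its E2 enzymes, 5 fell, 1 rose and 12 did not pass (10 fell and 4 rose adjusted over the list alone). Their median was -1.46 (camera adjusted p = 0.0103; adjusted p = 0.22 with an estimated correlation), a call lost on arrays centred on ribosomal protein genes, where the median was 1.70. That scaling lifts bright genes most, so this loss does not compare the list with genes of like signal. The call was also lost with the mean of all probe sets (median -0.94, adjusted p = 0.0674) and without the lowest 40% of genes (adjusted p = 0.0691). Cdc26, named after its values were seen, went against the list at 1.55 (adjusted p = 0.0447), a call lost without GV 3, MI 1, MI 2 or any of the 3 MII arrays (adjusted p from 0.0653 to 0.133). Anapc7 fell from 648 ± 171 to 59.8 ± 53.8 (log2 change -3.32; other, dimmer probe set 1.74). Of 45 spindle and kinetochore genes, 2 rose, 8 fell and 35 did not pass (2 rose and 12 fell adjusted over the list alone). Their median was 0.08 (camera adjusted p = 0.73). Tacc3, a microtubule-stabilising protein of the spindle, fell from 6868 ± 924 to 589 ± 417 (log2 change -3.94). Haus1 and Haus8, both subunits of the augmin complex, had -3.63 and -3.59. Tpx2 had a log2 change of 0.13 (adjusted p = 0.813).

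Regulators of translation and mRNA stability also moved both ways from MI to MII, with 5 of 49 rising, 6 falling and 38 not passing (11 and 10 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.271). Pan2, a poly(A) nuclease subunit, rose from 690 ± 271 to 2946 ± 665 (log2 change 2.12, adjusted p = 0.0126, n = 3 each). Ddx6, a helicase of repressed mRNAs, rose from 25.7 ± 18.0 to 315 ± 170 (log2 change 2.96; other probe sets 0.35, 0.14 and -0.26), a call lost without MI 1 (adjusted p = 0.0536) or MII 3 (adjusted p = 0.051). Pabpc1l, the oocyte poly(A)-binding protein, fell from 2834 ± 716 to 426 ± 198 (log2 change -2.77), and Sympk, a scaffold of the polyadenylation machinery, by 2.68. The list of mRNAs polyadenylated at maturation rose as a group, with 2 of 6 rising (2 adjusted over the list alone), all 6 above 0 and a median of 0.77 (camera adjusted p = 0.00215; adjusted p = 0.209 with an estimated correlation). Its risers were Plat, from 3773 ± 248 to 6491 ± 582 (log2 change 0.78, SE 0.18, adjusted p = 0.0362), and Btg4, from 5072 ± 901 to 10162 ± 242 (log2 change 1.02, SE 0.24, adjusted p = 0.0394). Both calls were fragile: Plat passed in only 1 of the 9 fits that left out 1 array, that without GV 3 (adjusted p from 0.0528 to 0.107 in the others), and Btg4 in only 2, those without GV 1 or GV 3 (adjusted p from 0.0617 to 0.101 in the others). Mos had a log2 change of 0.76 (adjusted p = 0.269) and Dazl one of 0.80 (adjusted p = 0.0693).

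The zona and maternal-effect lists fell as groups from MI to MII on the arrays as deposited, and their signs turned on arrays centred on ribosomal protein genes. Their medians were -0.46 and -0.28 after quantile normalization, where the maternal-effect list did not pass (adjusted p = 0.0733), and -0.48 and -0.33 with arrays scaled to the same 95th percentile. Without the lowest 40% of genes neither list passed (adjusted p = 0.0821 and 0.0921), and without MI 1 the zona median was -1.30. Of 13 zona pellucida and oocyte growth factor genes, 6 fell, 1 rose and 6 did not pass (6 fell and 2 rose adjusted over the list alone). Their median was -0.69 as deposited and 2.49 when centred on ribosomal protein genes, beside the shift of 2.12 (camera adjusted p = 0.00914; adjusted p = 0.324 with an estimated correlation). Zp3, an egg coat protein, fell from 7813 ± 155 to 1982 ± 834 (log2 change -2.07, SE 0.32, adjusted p = 0.00796, n = 3 each), against 1.21 when so centred. Zp1 fell from 4321 ± 847 to 1574 ± 436 (log2 change -1.46, against 1.82 when so centred) and Zp2 from 5976 ± 491 to 1696 ± 720 (log2 change -1.91, against 1.36), and both calls were lost without MI 2 (adjusted p = 0.0513 and 0.0547). The growth factor genes Gdf9 and Bmp15 did not pass, at -0.28 and -0.69, and were at 3.01 and 2.60 when so centred. The member that rose was Oosp3, named after its values were seen, at 1.11. Of 30 maternal-effect and subcortical complex genes, 7 fell, none rose and 23 did not pass (10 fell and 2 rose adjusted over the list alone). Their median was -0.53 as deposited and 2.74 when so centred (camera adjusted p = 0.00242; adjusted p = 0.209 with an estimated correlation). When so centred, the maternal-effect list passed as higher than other genes (camera adjusted p = 0.00598) and the zona list did not pass (camera adjusted p = 0.0878). That scaling lifts bright genes by more than dim ones. The call therefore does not place the maternal-effect list above genes of like signal and is no sign of a rise. Khdc3 fell from 3102 ± 1575 to 159 ± 85.6 (log2 change -4.15), Tle6 by 2.67 and Padi6 by 2.33, all parts of the structures beneath the egg surface, while Nlrp5 had -0.72 (adjusted p = 0.149). Of 21 oocyte transcription factor genes, 3 rose, 2 fell and 16 did not pass (3 and 2 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.258). Figla, which switches on the zona genes, fell from 1053 ± 279 to 20.1 ± 4.53 (log2 change -4.86, adjusted p = 0.000726), and Obox3 rose from 7.60 ± 4.47 to 47.4 ± 5.11, near background (log2 change 1.44).

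Smaller changes were seen in 3 further lists from MI to MII. Of 21 fertilisation and egg activation genes, 5 fell, none rose and 16 did not pass (6 fell and 1 rose adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.159; median 2.76 on arrays centred on ribosomal protein genes). They included Cd9, a membrane protein needed for sperm-egg fusion, which fell from 983 ± 458 to 64.8 ± 14.6 (log2 change -3.51, n = 3 each), and Izumo1r, which fell from 2024 ± 367 to 571 ± 138 (log2 change -1.81). Of 23 meiotic arrest and cAMP-MAPK genes, 3 rose, 3 fell and 17 did not pass (4 and 3 adjusted over the list alone). Their median was -0.01 (camera adjusted p = 0.469). Gnas, the stimulatory G protein that keeps cAMP high in arrested oocytes, fell from 2665 ± 441 to 698 ± 95.8 (log2 change -1.90), and Prkaca, a catalytic subunit of protein kinase A, rose from 554 ± 289 to 1753 ± 139 (log2 change 1.79), a call lost without MI 2 (adjusted p = 0.0659), MII 1 (adjusted p = 0.074), MII 2 (adjusted p = 0.0817) or MII 3 (adjusted p = 0.0758). Of 27 genes of the meiotic chromosome axis and recombination, only Msh4, a recombination protein, passed, rising from 299 ± 37.6 to 947 ± 170 (log2 change 1.60, adjusted p = 0.00544; list median -0.15, camera adjusted p = 0.73), and 1 passed adjusted over the list alone.

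The comparison of MII with GV spans the whole of maturation, 14 h after hCG against none. More genes passed than at the second step: 993 rose and 1601 fell by limma's test, of which 934 and 1573 changed at least 2-fold, and 992 and 1600 had their 3 arrays of one stage beyond the 3 of the other. The mRNAs that the study is known for rose over this span. Tex19.1 rose from 1695 ± 769 to 5751 ± 396 (SD, n = 3 each; log2 change 1.84, SE 0.31, adjusted p = 0.00694), Dazl from 857 ± 45.1 to 1913 ± 198 (log2 change 1.14, SE 0.23, adjusted p = 0.0132; other probe set 2.39) and Tpx2 from 1163 ± 171 to 2175 ± 342 (log2 change 0.89, SE 0.21, adjusted p = 0.0277). The other 3, dimmer probe sets of Tpx2 had -0.05, 0.08 and -0.07, and its call was lost without GV 2 (adjusted p = 0.0858), GV 3 (adjusted p = 0.0645), MII 1 (adjusted p = 0.0617) or MII 3 (adjusted p = 0.0857). Bub1b rose from 1795 ± 98.8 to 5967 ± 1906 (log2 change 1.68, adjusted p = 0.0053). Genes that rose made up 38.3% of those called, against 47.1% after quantile normalization, 48.1% with arrays scaled to the same 95th percentile and 99.5% on arrays centred on ribosomal protein genes. The count of genes that rose was 637 without GV 2, 617 without GV 3, 637 without MII 1 and 617 without MII 3.

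Genes that rose from GV to MII again started lower than genes that fell, with a median GV intensity of 224.1 against 1063.4 and 305 of 993 against 42 of 1601 below 100. Here too the order was partly fixed in advance, since the same GV arrays enter the calls. Among the largest rises, Cyp4v3, a fatty acid hydroxylase, went from 9.96 ± 3.21 to 516 ± 19.8 (log2 change 4.36, SE 0.31, adjusted p = 0.000654, n = 3 each). Fbxo15 went from 64.5 ± 57.7 to 1654 ± 1157 (log2 change 4.45), Camk1d, a calmodulin-dependent kinase, from 6.81 ± 0.555 to 542 ± 425 (log2 change 4.29), and Ust, a sulfotransferase of the extracellular matrix, from 3.47 ± 1.53 to 351 ± 158 (log2 change 4.14). Tmc7 rose by 4.27. Anapc10 rose from 97.4 ± 60.3 in GV to 1859 ± 515 in MII (log2 change 4.17, adjusted p = 0.00188), and its other probe set by 3.40. Prkci rose by 4.84, a call lost without MII 3 (adjusted p = 0.052), and Lamp2, a lysosomal membrane protein, by 4.48, a call lost without MII 1 (adjusted p = 0.0565) or MII 3 (adjusted p = 0.0593). Thsd7b had 4.37 at its brightest probe set and 0.30 and -0.42 at the others. Among the largest falls, Sdhb of respiratory complex II went from 2498 ± 1036 to 46.1 ± 67.8 (log2 change -5.83), Ndufv3 of complex I from 4770 ± 3256 to 74.5 ± 73.1 (log2 change -5.78) and Mrps28 from 2736 ± 1739 to 27.8 ± 37.4 (log2 change -6.07). Ndufb7 had -5.58, Spc24 -5.68 and Snapc5 -5.60. Aspscr1 had -7.07 at its brightest probe set against -0.11 at the other, and Pum3 had -7.07 against 0.87 and -0.74. Tsc22d4 had -5.95 against -0.07 and Tox2 -5.56 against 0.07.

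By list, the mRNAs polyadenylated at maturation rose from GV to MII, with 5 of 6 rising and the sixth above 0 (6 adjusted over the list alone). Their median was 1.19 (camera adjusted p = 3.39e-05; adjusted p = 0.15 with an estimated correlation). Mos rose from 929 ± 329 to 2520 ± 553 (log2 change 1.47, SE 0.36, adjusted p = 0.0297, n = 3 each), a call lost without GV 2 (adjusted p = 0.0646), GV 3 (adjusted p = 0.0796), MII 1 (adjusted p = 0.0843) or MII 2 (adjusted p = 0.0919). Btg4 rose by 1.43, Plat by 0.93, Slbp from 3935 ± 82.3 to 7658 ± 202 (log2 change 0.96) and Hprt, a purine salvage enzyme, by 2.04. Of the regulators of translation and mRNA stability, 11 of 49 rose, 9 fell and 29 did not pass (12 and 9 adjusted over the list alone). Their median was 0.66 (camera adjusted p = 0.0695). Tent2, a cytoplasmic poly(A) polymerase, rose from 134 ± 42.8 to 1261 ± 517 (log2 change 3.07), while Pabpc1l fell from 4032 ± 491 to 426 ± 198 (log2 change -3.30), Sympk fell by 3.52 and Cpeb1 fell from 2320 ± 179 to 732 ± 109 (log2 change -1.65, adjusted p = 0.00229, against 1.94 on arrays centred on ribosomal protein genes).

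Of the M-phase regulators, 6 of 34 rose, 8 fell and 20 did not pass from GV to MII (9 and 10 adjusted over the list alone), and the list's median of 0.22 and its mean of -0.26 differed in sign (camera adjusted p = 0.704). Cdk1 fell from 4040 ± 1423 to 76.9 ± 44.3 (log2 change -5.54, n = 3 each). Cdc25b had -4.17, Ensa -4.04 and Ccnb3, a cyclin of meiosis, -3.38. The call of Ccnb3 was lost without GV 1 (adjusted p = 0.0538), MII 2 (adjusted p = 0.0858) or MII 3 (adjusted p = 0.0993). Of the anaphase-promoting complex list, 2 of 18 rose, 6 fell and 10 did not pass (2 and 9 adjusted over the list alone). Their median was -1.49 (camera adjusted p = 0.0294; adjusted p = 0.299 with an estimated correlation), a call lost on arrays centred on ribosomal protein genes, where the median was 1.99. That loss, too, does not compare the list with genes of like signal. The call was also lost without GV 3 (camera adjusted p = 0.0549) or MII 3 (camera adjusted p = 0.0745), after quantile normalization (0.0502), with the mean of all probe sets (0.2), without _x_at and _s_at probe sets (0.117) and without the lowest 40% of genes (0.123). Anapc10, above, and Cdc27, named after its values were seen and at 2.25, went against the list, and Anapc7 fell by 3.78 (other, dimmer probe set 1.75). Of 45 spindle and kinetochore genes, 7 rose, 9 fell and 29 did not pass (13 and 14 adjusted over the list alone). Their median was -0.05 (camera adjusted p = 0.854). Tacc3 fell by 4.05 and Haus8 by 4.09. Of the meiotic arrest list, 2 of 23 rose, 4 fell and 17 did not pass (5 and 5 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.949), with Ppp1ca, a catalytic subunit of protein phosphatase 1, at -3.60 and Gnas at -2.13.

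Ribosomal and mitochondrial mRNAs had fallen furthest by MII. Of 50 cytosolic ribosomal protein genes, 39 fell, none rose and 11 did not pass from GV to MII (43 fell adjusted over the list alone), with a median 10.6-fold lower (log2 change -3.40; camera adjusted p = 6.41e-27; adjusted p = 0.115 with an estimated correlation). Of 82 oxidative phosphorylation genes, 63 fell, none rose and 19 did not pass (69 fell and 1 rose adjusted over the list alone). Their median was -3.26 (camera adjusted p = 5.74e-30; adjusted p = 0.115 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes, 40 fell, 1 rose and 35 did not pass (52 and 3 adjusted over the list alone). Their median was -2.28 (camera adjusted p = 4.4e-15; adjusted p = 0.115 with an estimated correlation). Proteasome subunits fell in 20 of 39 cases, rose in none and did not pass in 19 (24 and 2 adjusted over the list alone). Their median was -1.45 (camera adjusted p = 3.09e-08; adjusted p = 0.15 with an estimated correlation). Initiation and elongation factors fell in 26 of 58, rose in 1 and did not pass in 31 (28 and 1 adjusted over the list alone). Their median was -1.06 (camera adjusted p = 2.81e-06; adjusted p = 0.155 with an estimated correlation). Tricarboxylic acid cycle genes fell in 9 of 22 and did not pass in 13 (11 adjusted over the list alone). Their median was -1.29 (camera adjusted p = 0.00233; adjusted p = 0.209 with an estimated correlation). With the mean of all probe sets the mitochondrial ribosomal, initiation and elongation and tricarboxylic acid lists had smaller medians, -1.38, -0.69 and -0.74, and still passed. Examples were Rpl27a at -4.83 (other, dimmer probe set 1.29), Rpl7 at -4.52, Rps19 at -4.48, Ndufb5 at -4.99, Mrpl33 at -4.77, Psmb5 at -4.12, Eif3k at -4.06 and Dlst, a subunit of 2-oxoglutarate dehydrogenase, at -3.87. On arrays centred on ribosomal protein genes the medians of these 6 lists were 0.06, 0.28, 1.18, 1.58, 2.23 and 2.24 beside the shift of 2.23, and only the first 3 passed as lower than other genes. Since that scaling lifts bright genes most, the lost calls do not tell how the other lists moved against genes of like signal.

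Both the zona and the maternal-effect list had negative medians from GV to MII as deposited, and both calls were lost after quantile normalization (medians -0.37 and -0.26, adjusted p = 0.0502 and 0.141) and without the lowest 40% of genes (adjusted p = 0.0926 and 0.123). With arrays scaled to the same 95th percentile their medians were -0.48 and -0.31. The maternal-effect call was also lost with pseudocount 1 (camera adjusted p = 0.0519). The zona and growth factor list fell in 6 of 13 cases, rose in 2 and did not pass in 5 from GV to MII (6 and 2 adjusted over the list alone). Their median was -0.70 as deposited and 2.92 on arrays centred on ribosomal protein genes (camera adjusted p = 0.0124; adjusted p = 0.327 with an estimated correlation). Zp1 fell from 5485 ± 407 to 1574 ± 436, Zp2 from 7683 ± 838 to 1696 ± 720 and Zp3 from 8694 ± 794 to 1982 ± 834 (log2 change -1.82, -2.27 and -2.22, n = 3 each), against 1.79, 1.34 and 1.40 when so centred. The risers were Oosp1 and Oosp3, oocyte-secreted proteins named after their values were seen, at 1.11 and 1.43. Gdf9 (-0.46, adjusted p = 0.179) and Bmp15 (-0.70, adjusted p = 0.178) did not pass. The maternal-effect list fell in 10 of 30 cases, rose in 3 and did not pass in 17 (12 and 3 adjusted over the list alone). Their median was -0.52 as deposited and 3.08 when so centred (camera adjusted p = 0.00629; adjusted p = 0.228 with an estimated correlation). When so centred, it passed as higher than other genes (camera adjusted p = 0.00357), and the zona list did not pass (camera adjusted p = 0.0648). As bright genes are lifted most by that scaling, the call does not place the maternal-effect list above genes of like signal. Khdc3 fell by 4.09, Tle6 by 2.85 and Padi6 by 2.81, and Nlrp5, a core protein of the subcortical complex, fell from 8310 ± 796 to 3640 ± 1097 (log2 change -1.23, adjusted p = 0.0174, against 2.39 when so centred), a call lost without GV 2 (adjusted p = 0.0568) or GV 3 (adjusted p = 0.055). The risers Ctcf, Tcl1 and Tet3, also named after their values were seen, had 1.33, 1.52 and 1.31. The call of Ctcf was lost in 7 of the 9 fits that left out 1 array, all but those without MI 1 or MI 3 (adjusted p from 0.0525 to 0.124), that of Tcl1 without MII 3 (adjusted p = 0.0553) and that of Tet3 without GV 1, GV 2, MII 2 or MII 3 (adjusted p from 0.0521 to 0.0539).

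Of the oocyte transcription factors, 5 of 21 rose, 2 fell and 14 did not pass from GV to MII (5 and 4 adjusted over the list alone). Their median was 0.54 (camera adjusted p = 0.0778). Obox5, a homeobox protein of oocytes, rose from 1439 ± 306 to 6194 ± 263 (log2 change 2.12, adjusted p = 0.00224, n = 3 each), while Figla fell by 5.00 and Nobox, a regulator of oocyte genes, from 3948 ± 639 to 634 ± 578 (log2 change -2.97). Of 27 chromosome axis and recombination genes, Msh4 and Tex19.1 rose and 25 did not pass (2 adjusted over the list alone). Their median was 0.03 (camera adjusted p = 0.326). Of 21 fertilisation genes, 5 fell, none rose and 16 did not pass (6 and 2 adjusted over the list alone). Their median was -0.18 (camera adjusted p = 0.259), with Izumo1r falling from 4982 ± 701 to 571 ± 138 (log2 change -3.10) and Cd9 by 3.87.

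Sorted by their calls over time, 394 genes rose and 1071 fell both from MI to MII and from GV to MII, against 25.2 and 108.5 for independent lists of these sizes. Both comparisons use the same MII arrays, so part of this excess may come from the shared arrays. Another 599 genes rose and 530 fell from GV to MII without passing at either single step, 68 rose and 162 fell from MI to MII alone, and 15369 had no call. Across genes, the log2 changes of MI to MII and GV to MII correlated at r = 0.862 with a covariance of 1.16 (simulated 0.139). Those of GV to MI and MI to MII correlated at r = -0.036 with a covariance of -0.0244 (simulated -0.138). Tested directly, the change from MI to MII differed from that from GV to MI for 38 genes by limma, 2 toward a rise and 36 toward a fall, among them Ensa, Figla, Eif1b, Rpl7, Rpl10a and Mrps18c. The difference between the steps called 8 genes after quantile normalization, 12 with arrays scaled to the same 95th percentile, 14 without the lowest 40% of genes, 95 over every probe set, 6 with pseudocount 1, 124 with pseudocount 64 and none without GV 3 and MI 3. The count also rests on single arrays: it was 2 without GV 1, GV 2, MI 2 or MII 3, 3 without GV 3 or MI 1, 9 without MI 3 or MII 2 and 70 without MII 1. It did not hold with the replicate number as a block either, as the part on processing gives.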

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

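Of the tests below, that of less labelled target on the MII arrays and that of RNA from granulosa and other somatic cells were chosen only after the result was seen.

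A direct test of the difference between the 2 steps found 38 genes whose change from MI to MII differed from that from GV to MI (limma, adjusted p under 0.05, 2060 at an unadjusted p under 0.05). Among the genes named in the report, Ndufb7 had a difference of -5.18 (SE 0.38, adjusted p = 0.00737), Tox2 of -5.83 (adjusted p = 0.0311), Tsc22d4 of -5.86 (adjusted p = 0.0371) and Poglut2 of 6.91 (adjusted p = 0.0391), with 3 arrays per stage. For Tox2 and Tsc22d4 the other probe set lay above 0 from MI to MII, at 0.63 and 0.89. Of 100 splits of the 9 arrays into 3 groups, 2 called as many genes as the real 38, the real one among them, and the highest other called 88. Each division of the arrays was counted in only 1 order of its groups, while this contrast depends on which group is the middle one. The real division with MII in the middle was never counted. The share of splits therefore decides nothing about chance, and it does not bear on whether the 2 steps were equal. The split with 88 genes kept the 3 MII arrays together. The count also depends on the fit, as the part on processing gives. Without GV 1, GV 2, MI 2 or MII 3 the count was 2, without GV 3 or MI 1 it was 3, without MI 3 or MII 2 it was 9 and without MII 1 it was 70.

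Probe sets with no gene symbol or with several were outside the tests of genes, and some of them changed. By limma, of 10092 such probe sets, 235 passed from MI to MII (36 higher, 199 lower) and 320 from GV to MII (99 higher, 221 lower), against 3 from GV to MI. The hybridisation controls, added to every array, were also outside those tests: their geometric mean was 5143 on MI 3, against 2000.53 to 3588.65 on the other 8 arrays.

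The mRNAs of cytosolic ribosomal proteins and of oxidative phosphorylation fell from MI to MII, with a median of -3.06 on the log2 scale over their 132 genes. Less labelled target would lower these lists where controls are high, but on GV 3 and MI 3, whose mean control signals (11.81 and 12.33 on the log2 scale) exceeded every MII array's (up to 11.43), the lowest median of the 2 lists was 10.24, against at most 8.55 on an MII array. Probe sets marked as shared between transcripts did not carry the fall. Without _x_at and _s_at probe sets, 45 ribosomal protein and 78 oxidative phosphorylation genes were left, and the weaker of the 2 list medians was -2.80. Probe sets without these suffixes can cross-hybridise too, so this does not exclude cross-hybridisation. Compression of all bright genes would give a like fall elsewhere, but 1576 genes outside the lists with like MI signal had a median of -0.54, with 62.7% lower, and the weaker list median was still -2.85 after quantile normalization and -2.81 with the same 95th percentile. These values argue against less labelled target and against compression of all bright genes, while cross-hybridisation stays open. A loss of these mRNAs from polysomes may be one hypothesis. Decay of the mRNAs and a lower amount of polysomal RNA in MII oocytes stay open and untested. The poly(A) tail and amplification, named below for genes that rose, were not tested for this fall either.

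Of the 993 genes that rose from GV to MII, 305 started below an intensity of 100 in GV, and if single probe sets misbehaved their other probe sets would not follow, but 67.7% of all 356 rose, against 53.0% of 6903 of genes not called (one-sided permutation p = 1e-05, the smallest that 1e+05 resamples can give). The permutation treated probe sets as independent, though all share the same arrays and some share a gene. Its p therefore does not measure the spread between arrays. Somatic cells would bring their abundant mRNAs, but the higher of the 2 marker list medians from GV to MII was 0.063. Of 28 granulosa, cumulus and theca and 14 blood, immune and endothelial markers, 0 of which are in another list, 2 and 2 had an intensity of 100 or more in GV and 1 and 1 in MII. Among them, Cyp11a1 stood at 531 ± 351 in GV and 163 ± 202 in MII, Tek at 369 ± 160 and 21.1 ± 22.8, and Pecam1 at 190 ± 104 and 661 ± 112 (n = 3 each; log2 change -1.98, -3.44 and 1.83; adjusted p = 0.248, 0.00609 and 0.153). Entry of stored mRNA into polysomes may be one hypothesis, and a longer poly(A) tail that favours amplification stays open and untested; the other probe sets had a median of 0.27, with 113 of 356 at or above the median signal of all genes, so single genes may still rest on 1 probe set.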

How the results depend on the processing

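Alternatives were set before the data were examined, except for leaving out GV 3 and MI 3 together and scaling to the same 95th percentile. The median, trend and robust, mean of all probe sets, at least 2-fold, 2-group and without _x_at and _s_at alternatives kept each count of genes within 1.5 times of the first one, and no alternative called a gene from GV to MI. For fits of only the 2 groups compared, the F test and the difference between the 2 steps have no value. The number of arrays and the share of probe sets near background limit precision.

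With the replicate block, the counts were 471 higher and 1220 lower in MII than in MI, 1004 and 1642 against GV, 2010 in the F test and 32 list tests, and the difference between the 2 steps called 0 genes. Arrays with the same number correlated at 0.0091 to 0.209 in their deviations, 5 of 9 pairs above 0.1, and those with different numbers at -0.232 to 0.105. The bound set for pairing, every same-number correlation above 0.1, was not met, so the block stayed an alternative. That 7 of 9 arrays matched their own number best is a hint from the data, not the design.

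Centring on ribosomal protein genes shifts all genes upward by its construction, so signs turn with it: 13813 genes were higher and 73 lower in MII than in MI, 14281 and 68 against GV, with 13571 in the F test and 5569 between the steps. From MI to MII the medians turned to 2.49 for the zona list and 2.74 for the maternal-effect list, and Cpeb1, Zp1, Zp2 and Zp3 to 1.23, 1.82, 1.36 and 1.21. From GV to MII they turned to 2.92 and 3.08, with 2.76 for the endoplasmic reticulum list, and to 1.94, 1.79, 1.34 and 1.40, with 2.39 for Nlrp5. Without _x_at and _s_at probe sets Tox2 had 0.63 and 0.070, since another probe set then stands for it.

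Genes higher in MII than in MI numbered 828 after quantile normalization, 781 with the same 95th percentile, 707 over every probe set and 183 with pseudocount 1. Those higher in MII than in GV numbered 1690 over every probe set and 621 with pseudocount 1, and the F test called 3165 probe sets. The difference between the steps called 8 genes after quantile normalization, 12 with the same 95th percentile, 95 over every probe set, 14 without the lowest 40% of genes, 6 with pseudocount 1, 124 with pseudocount 64 and 0 without GV 3 and MI 3. At an adjusted p under 0.01, by construction fewer genes passed: 70 higher and 463 lower from MI to MII (533 in the time patterns), 344 and 764 from GV to MII, 727 in the F test and 2 between the steps. With an estimated correlation 0 of 84 list tests passed, against 30 with the preset one and 28 by fry. Apart from the shift and the thresholds, the cause was not tested.

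Leaving out 1 array at a time gave 187 to 438 genes higher and 640 to 1197 lower in MII than in MI, 617 to 1131 higher and 1138 to 1716 lower in MII than in GV, 1140 to 2248 in the F test, 2 to 70 between the steps and 26 to 31 list tests. Of the named genes, 61 of 108 calls from MI to MII and 87 of 118 from GV to MII passed in each of the 9 fits.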

Other observations

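Of the tests in this part, that of a fit without GV 3 and MI 3 was added after the data were seen.

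Lists outside the report are described at the step named with each. Of 46 genes of the endoplasmic reticulum and secretory pathway, 5 rose, 16 fell and 25 did not pass from GV to MII (6 and 18 adjusted over the list alone). Their median was -0.65 as deposited and 2.76 on arrays centred on ribosomal protein genes (camera adjusted p = 0.0115; adjusted p = 0.324 with an estimated correlation). Cope, a subunit of the COPI coat, fell from 1578 ± 585 to 54.9 ± 37.8 (log2 change -4.55, n = 3 each) and Ssr4, of the translocon, by 3.68 (other, dimmer probe sets 0.09 and 0.12). The list's call was lost after quantile normalization (adjusted p = 0.0781), with the mean of all probe sets (adjusted p = 0.0535) and without the lowest 40% of genes (adjusted p = 0.0902), and the list did not pass from MI to MII (median -0.32, camera adjusted p = 0.0778). Ssr3, also of the translocon, rose from 537 ± 619 to 4209 ± 595 (log2 change 3.61), a call lost without GV 3 (adjusted p = 0.0582), MII 1 (adjusted p = 0.0543) or MII 3 (adjusted p = 0.0504). Of 20 stress and heat-shock genes, 2 fell, none rose and 18 did not pass from MI to MII (4 fell adjusted over the list alone), with Ddit3, a stress transcription factor, going from 603 ± 210 to 23.2 ± 21.4 (log2 change -4.06). Their median was -0.45 (camera adjusted p = 0.0315; adjusted p = 0.209 with an estimated correlation; 1.54 on arrays centred on ribosomal protein genes, below the shift of all genes), a call lost without MI 3 (median -0.20, camera adjusted p = 0.207) or MII 2 (camera adjusted p = 0.0815). It was also lost without the lowest 40% of genes (median -0.84, adjusted p = 0.0751), and the median was -0.26 with pseudocount 64. From GV to MII the stress list did not pass (median -0.46, camera adjusted p = 0.0596). Of 48 DNA replication genes, 3 rose, 11 fell and 34 did not pass from MI to MII (6 and 15 adjusted over the list alone; median -0.14, camera adjusted p = 0.159; 0.04 after quantile normalization), with Fen1, a flap nuclease, falling from 2101 ± 811 to 77.1 ± 26.0 (log2 change -4.46). Of 16 glycolysis genes, 2 fell and 14 did not pass from MI to MII (2 adjusted over the list alone; median -0.35, camera adjusted p = 0.271; 1.98 on arrays centred on ribosomal protein genes). They included Pkm, pyruvate kinase, at -2.17 (adjusted p = 0.0284), a call lost without MI 1, MI 2, MI 3, MII 1 or MII 3 (adjusted p from 0.0677 to 0.0842), and Tpi1, triosephosphate isomerase, at -3.75, a call lost without MI 1, MI 2, MI 3, MII 2 or MII 3 (adjusted p from 0.0576 to 0.0865).

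The list median of chromatin modifiers lay higher on all 3 MII arrays than on the other 6, at 0.37 from MI to MII (camera adjusted p = 0.0199; adjusted p = 0.324 with an estimated correlation; adjusted p = 0.101 by fry), though only 2 of 40 genes rose and 2 fell (6 and 2 adjusted over the list alone). That call was lost without MI 3 (median 0.14, camera adjusted p = 0.0846), without MII 1 (median 0.31, camera adjusted p = 0.0652) and with pseudocount 1 (0.0515), and the median was 0.65 after quantile normalization, 0.58 with the same 95th percentile and 0.60 without _x_at and _s_at probe sets. From GV to MII the median was 0.63 (camera adjusted p = 0.0286; adjusted p = 0.324 with an estimated correlation; adjusted p = 0.0534 by fry), a call lost without GV 1 (0.0556), MII 1 (0.0652) or MII 3 (0.0523), without the lowest 40% of genes (0.0688) and with pseudocount 1 (0.0996). Kat5, a histone acetyltransferase, fell from 939 ± 143 in MI to 63.7 ± 45.7 in MII (log2 change -3.71, n = 3 each) and Cbx2, a Polycomb protein, rose by 1.96. The PI3K-mTOR list had a median of 0.69 from MI to MII and no gene called of 21 (none adjusted over the list alone; camera adjusted p = 0.0146; adjusted p = 0.259 with an estimated correlation; adjusted p = 0.0799 by fry). That call was lost without MI 3 (median 0.37, camera adjusted p = 0.121) and with the mean of all probe sets (median 0.25, adjusted p = 0.0532), and the median was 0.43 without MII 1. Nuclear pore and lamina genes moved both ways from MI to MII (1 rose and 7 fell of 30; 4 and 9 adjusted over the list alone; median 0.19, mean -0.04, camera adjusted p = 0.824), with Nup133 falling by 2.71. DNA damage and repair genes (1 rose, 2 fell of 31, the same counts adjusted over the list alone; median -0.03, camera adjusted p = 0.633; 0.17 after quantile normalization) and histone genes, variants and chaperones (none rose, 1 fell of 15, none adjusted over the list alone; median -0.11, camera adjusted p = 0.857; 0.12 after quantile normalization) moved little as lists. Granulosa, cumulus and theca markers had a median of -0.31 (camera adjusted p = 0.419; 1.79 on arrays centred on ribosomal protein genes; 0.015 without MI 3) and blood, immune and endothelial markers one of 0.18 (camera adjusted p = 0.759). The median of the granulosa, cumulus and theca markers was 5.72 on MI 3, against 4.77 to 4.97 on the other 8 arrays. Tek, an endothelial receptor, went from 361 ± 197 in MI to 21.1 ± 22.8 in MII (log2 change -3.39, adjusted p = 0.00961).

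No gene passed limma's test from GV to MI (1308 at an unadjusted p under 0.05), yet genes that passed from GV to MII had part of their change at MI. Had all of it come after MI, shared GV arrays would give at most 9.22% of the change of genes that rose and 5.61% of that of genes that fell in simulations, but the medians were 31.8% and 13.1%, with 89.6% and 73.0% of genes having the same sign at MI against at most 65.4% and 60.9% in the simulations. The simulated noise was independent between genes, whereas genes on one array can deviate together. The simulated limits may thus be too narrow, and the excess does not exclude that all of the change came after MI. A gradual change that starts before MI may be one hypothesis. Low power fits the lack of calls, since 12% of simulated 4-fold changes were recovered with 100 genes above the median signal changed at each fold. That share depends on how many genes change, and other numbers were not simulated. Leaving out GV 3 and MI 3, which had the highest control signal of their stages, gave 0 genes, which decides nothing, because that fit sets 2 arrays against 2 and has less power; the bound of 50 genes set for it was wrong for this reason.

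Other splits of the same arrays were counted for each comparison. For the single steps there are 10 splits, too few for a share under 0.05: from GV to MI all 10 called at least the real 0 (highest other 2), from MI to MII 1 of 10 reached the real 1695 (highest other 1) and from GV to MII 1 of 10 reached the real 2594 (highest other 0). For the F test over the 3 stages, 1 of 100 splits reached the real 2108 and the highest other called 1661. The splits with 1661 and 1633 genes kept the 3 MII arrays together and mixed GV with MI arrays. The count thus excludes chance only against no difference among the stages at all, and does not bear on GV against MI.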
